A study of Entamoeba invadens with 4 samples.

How the data were processed

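Total RNA from 4 samples of encysting Entamoeba invadens was enriched for mRNA and sequenced in paired-end mode with a TruSeq RNA v2 kit, per the labels' protocols. The labels assign 2 libraries to 200 nM trichostatin A (TSA) and 2 to ethanol, each for 24 h. Per the submitters' processing notes, Trimmomatic 0.36.5, TopHat2 2.0.11 and Cufflinks 2.2.1 were used; the genome build, the annotation, the library scaling and the dispersion model are not given in the sources used here. The 1 deposited table is a Cuffdiff test at the level of assembled transcripts, per the file headers. It names TSA as the first and ethanol as the second condition in every line.

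The deposited expression values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), 1 value per condition, which the authors' Cuffdiff run estimated from both libraries of that condition. The deposited log2 fold change is ethanol over TSA; its sign was turned so that positive values mean higher with TSA. In 4 lines the deposited log2 fold change differed from the log2 ratio of the 2 FPKM values by more than 0.01. The deposited test statistic is Cuffdiff's score per transcript and was used only in an alternative. The deposited p-values have a floor of 5e-05, reached by 4006 of 9995 tests (40.1%), and the deposited q-values are the Benjamini-Hochberg adjustment over those 9995 tests, as a recomputation showed. The table's own flag for a significant test equals a q-value of 0.05 or less with a completed test in all 14375 lines. Cuffdiff left 2880 transcripts untested for want of reads and 1500 for low data. FPKM keeps no read depth, so the depth per library is unknown and no counting interval or floor could be given for an expression value. Assembled transcripts shorter than a sequenced fragment have uncertain FPKM.

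No count model was fitted, because the table holds neither counts nor library values. The design fixed before the data were examined foresaw this, and it took the authors' calls as the main test of the comparison. Fold changes were also computed as log2((TSA + 1)/(ethanol + 1)), which understates the change of transcripts with low FPKM. The gene lists fixed beforehand (35 lists matched by product name) could not be applied: all 12007 locus tags in the table were found in the RefSeq table of assembly EIA2 v2, which gives no product names or symbols other than the tags. No list was therefore tested. The rule for genes named in the text, fixed beforehand, falls in that case to at most 2 called genes that rose most and 2 that fell most, among those with at least 1 FPKM in 1 condition.

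The transcript classes were chosen after the data were examined. They are unannotated transcripts (no annotated gene in the table), annotated transcripts on contigs with 30 annotated genes or fewer (410 of 488 contigs with an annotated gene, 238 of them with a tested transcript), genes more than 1000 bp from the nearest annotated gene, and loci over 2000 bp or up to 1000 bp. Positions are the table's loci, counted from 1; a locus can span several overlapping genes, so the length and distance of annotated genes were taken only from loci with 1 transcript. The share of called transcripts was compared with two-sided Fisher's exact tests (class against the other tested transcripts, both directions, 10 tests, Benjamini-Hochberg adjusted), with conditional odds ratios and exact 95% confidence intervals. Each class median was placed among the medians of 10000 random lists matched in 10 bins of mean expression. Intervals of rho and of median differences came from 1000 bootstrap samples of genes. Correlations of neighbouring loci were set against 200 random orders and stretches of loci called in 1 direction against 1000.

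These calculations were tested on simulated data made from the 9995 tested transcripts. Fold changes and calls were shuffled over transcripts and class members drawn at random. The simulations therefore do not cover classes made of neighbouring loci with correlated changes. A shift of 0.25 on the log2 scale planted in 200 transcripts put the list above the 97.5th percentile in 90% of 20 simulations, and shifts of 0.5 and 1 did so in 100%. With no shift, 1% of 100 lists fell outside the central 95%. The interval of the odds ratio held a planted value of 2 in 98 of 100 simulations. Alternatives covered the q threshold, a minimum fold, minimum FPKM, Bonferroni adjustment, 3 other scalings, 1 line per gene, pseudocounts of 0.1 and 5, calls from the test statistic, and other bounds of the classes. Leaving out a library was not possible with condition values only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.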

Results

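RNA sequencing was performed on encysting cultures of Entamoeba invadens, a reptile parasite that serves as the laboratory model for cyst formation in Entamoeba. Cells of strain IP-1 were placed in encystation medium for 24 h with either ethanol, the solvent control, or 200 nM trichostatin A (TSA), a hydroxamic acid that inhibits class I and class II histone deacetylases. The series holds 2 libraries per condition, 4 in all. The treatment labels name the treated material as cysts. The single comparison asks which transcripts differ between TSA-treated and solvent-treated cultures at 24 h. The share of encysted cells per library was not analysed here, so a difference in that share cannot be told apart from a change per cell. The authors' deposited table gives 1 FPKM value per condition and the Cuffdiff test for 14375 assembled transcripts, of which 13522 belong to 12007 annotated genes and 853 match no annotated gene. Values of single libraries and read depths were not analysed here, so no standard deviation accompanies an FPKM value, and the spread between libraries enters only through the authors' p-values. The labels do not say whether the libraries came from separate cultures, and those p-values may therefore measure technical spread alone.

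TSA-treated cells differed from solvent-treated cells in a large part of the transcripts that could be tested. Of 9995 transcripts with a completed test, 6295 (63.0%) passed an adjusted p of 0.05 in the authors' deposited table; 3331 of them were higher with TSA and 2964 were lower. With calls taken from the table's test statistic instead of its p-value, 4520 (45.2%) passed, 2454 higher and 2066 lower. The transcripts called higher by the deposited p had a median of 62.8 FPKM with TSA and 26.4 FPKM with ethanol. Those called lower had a median of 16.4 FPKM with TSA and 53.1 FPKM with ethanol. Moderate changes went both ways in similar numbers, with 2008 transcripts called higher by at least 2-fold and 1903 called lower by at least 2-fold. The remaining 3700 tested transcripts did not pass the threshold.

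With the deposited scaling, the largest changes were more often losses of abundant transcripts than rises. At least 8-fold changes were called for 394 transcripts that were lower with TSA and 252 that were higher, and at least 64-fold changes for 65 that were lower and 14 that were higher. The transcripts lower by at least 8-fold were abundant in the control, with a median of 224 FPKM with ethanol and 8.25 FPKM with TSA. The transcripts higher by at least 8-fold were scarce in the control, with a median of 1.84 FPKM with ethanol and 26.9 FPKM with TSA. A called fall from at least 1000 FPKM to under 10 FPKM occurred in 13 transcripts, and the opposite change in 0. A called rise from under 1 FPKM to at least 10 FPKM occurred in 32 transcripts, and the opposite change in 12. The median change over all tested transcripts was 0.07 on the log2 scale (quartiles -0.74 and 0.80), computed as log2 of TSA over ethanol with 1 FPKM added to each value.

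The balance between directions depended on the scaling of the 2 conditions. The summed FPKM was 0.26 higher with TSA on the log2 scale, and loci of 300 bp or less, whose FPKM is least certain, held 60.7% of that sum with TSA and 45.3% with ethanol. Rescaling each condition to 1 common sum lowers every log2 ratio of the FPKM values, with nothing added, by 0.26. Among called transcripts that then differed by at least 2-fold, 38.2% were higher with TSA, against 51.3% with the deposited scaling. When only loci longer than 300 bp were set to a common sum, the share was 60.9%. Among changes of at least 8-fold, falls outnumbered rises under each of these scalings. The margin was wide with 1 common sum (487 lower, 193 higher) and narrow with loci over 300 bp set to a common sum (348 lower, 322 higher). Among changes of at least 4-fold the balance turned: 807 lower and 682 higher with the deposited scaling, 693 lower and 852 higher with the scaling over loci over 300 bp. No called transcript changed direction, because the smallest called change was 0.39 on the log2 scale.

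**Figure D1:**
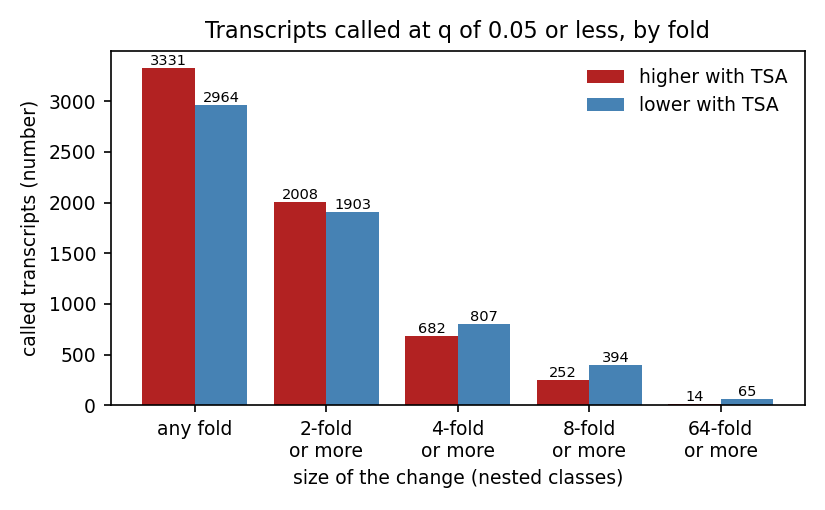
Number of transcripts (y axis) called higher or lower with TSA at an adjusted p of 0.05 or less, by the size of the change (x axis; each class contains the classes to its right). Rises outnumber falls over all calls (3331 against 2964), and falls outnumber rises among changes of at least 64-fold (65 against 14). Among annotated transcripts alone, the numbers over all calls are nearly equal (2863 higher, 2841 lower).

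Gene names could not be attached to these changes, because the reference table pairs all 12007 locus tags only with themselves. The annotated genes with the extreme changes are therefore given by locus tag, with positions on the contigs as the deposited table names them. The table does not name its genome build. The genes were ranked by the log2 change with 1 FPKM added to each value, while the log2 changes printed here are the deposited ones. A called rise from an ethanol value listed at 0 has no finite deposited log2 change and would rank above the rises given here. Each of these 4 genes is annotated as protein coding, and each had 1 assembled transcript. In the authors' deposited table, EIN_173210 (contig KB207112, 572418 to 572774) fell from 11357 FPKM with ethanol to 2.22 FPKM with TSA, a log2 change of -12.32 (Cuffdiff adjusted p = 0.00727). EIN_135840 (contig KB207027, 185298 to 185636) fell from 9389 FPKM to 3.15 FPKM in the authors' deposited table, a log2 change of -11.54 (Cuffdiff adjusted p = 0.00823). EIN_119110 (contig KB206391, 263215 to 263619) rose from 17.5 FPKM to 2321 FPKM in the authors' deposited table, a log2 change of 7.05. EIN_530690 (contig KB206706, 33244 to 33747) rose from 4.18 FPKM to 458 FPKM in that deposited table, a log2 change of 6.78. Both rises had the smallest adjusted p that the table holds, 0.000125. All 4 loci are short, between 339 and 504 bp, a length at which FPKM estimates are sensitive to the assumed fragment length.

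Transcripts outside the annotation rose far more often than annotated ones. Of 783 tested unannotated transcripts, 468 (59.8%) were called higher with TSA and 123 (15.7%) lower. Of 9212 tested annotated transcripts, 2863 (31.1%) were called higher and 2841 (30.8%) lower. The odds of a higher call were 3.29 times those of annotated transcripts (95% confidence interval 2.83 to 3.84; two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 2.12e-55 over 10 tests), and the odds of a lower call were 0.418 times (0.340 to 0.510; adjusted p = 1.12e-20). Unannotated transcripts had a median of 23.4 FPKM with TSA and 11.9 FPKM with ethanol, a median log2 change of 0.90 against 0.02 for annotated transcripts. The median of 0.90 exceeded all of 10000 random lists of annotated transcripts matched on mean expression, whose highest median was 0.15. Transcripts are not independent replicates, and these intervals and p-values describe the called transcripts of these libraries.

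Within the unannotated class, location made a difference. Of 534 unannotated transcripts more than 1000 bp from the nearest annotated gene on their contig, 64.8% were called higher with TSA and 13.3% lower. Of 184 that overlapped an annotated gene or lay within 1000 bp of one, 45.1% were called higher and 23.9% lower, and the odds ratio of a higher call between these 2 groups was 2.24 (95% confidence interval 1.57 to 3.19). A further 65 lay on contigs with no annotated gene, and 60.0% of these were called higher. Contig type made a difference too. On contigs with 30 annotated genes or fewer, those 65 included, 68.6% of 411 were called higher. On contigs with more genes the share was 50.0% of 372. Distance and contig type were not separated. The library kit named in the labels does not keep strand, so transcription antisense to a gene could not be separated from the gene itself.

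Annotated genes on contigs with few genes, and genes far from their neighbours, were also called higher more often than other annotated genes. Of 1111 tested annotated transcripts on contigs that carry 30 annotated genes or fewer, 610 (54.9%) were called higher with TSA and 223 (20.1%) lower. These contigs carry 2429 annotated genes in all, so most had no completed test. A gene with few reads in ethanol may enter the tested set only through reads gained with TSA, which favours higher calls. On contigs with more genes, 2253 of 8101 (27.8%) were called higher and 2618 (32.3%) lower. The odds ratio of a higher call was 3.16 (95% confidence interval 2.78 to 3.60; two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 2.04e-68). The median log2 change was 0.72 on the contigs with few genes and -0.04 on the others, and none of 10000 lists matched on mean expression reached 0.72 (highest 0.02). Genes whose nearest annotated neighbour lay more than 1000 bp away were called higher in 48.5% of 1024 cases, against 33.1% of 6321 genes with a closer neighbour (odds ratio 1.91, 95% confidence interval 1.66 to 2.18; two-sided Fisher's exact test, adjusted p = 1.10e-20). Among the 99 genes with no annotated neighbour within 5000 bp, 64.6% were called higher and 15.2% lower. The same gene can be in both classes, and distance and contig type were not separated here either. Contig length was not analysed. These tests and random lists count transcripts as independent. The first class is set per contig, with 238 contigs holding its tested transcripts, and changes of neighbouring loci were correlated. The intervals and p-values given here therefore understate the uncertainty.

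Long genes fell more often than short ones. This comparison used the 7395 tested annotated genes that stood alone in their locus with 1 transcript. Of 1356 genes with a locus longer than 2000 bp, 624 (46.02%) were called lower with TSA and 329 (24.3%) higher. Of 3350 genes with a locus of 1000 bp or less, 962 (28.7%) were called lower and 1307 (39.0%) higher. The odds ratio of a lower call for loci over 2000 bp was 1.90 against all shorter loci (95% confidence interval 1.68 to 2.15; two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 6.81e-25). Across genes, which are not independent replicates, Spearman's rho between locus length and log2 change was -0.12 (bootstrap 95% interval -0.14 to -0.10). The excess of lower calls was not seen when calls were taken from the table's test statistic instead of its p-value (odds ratio 0.958, 0.833 to 1.10), while rho does not use the calls.

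**Figure D2:**
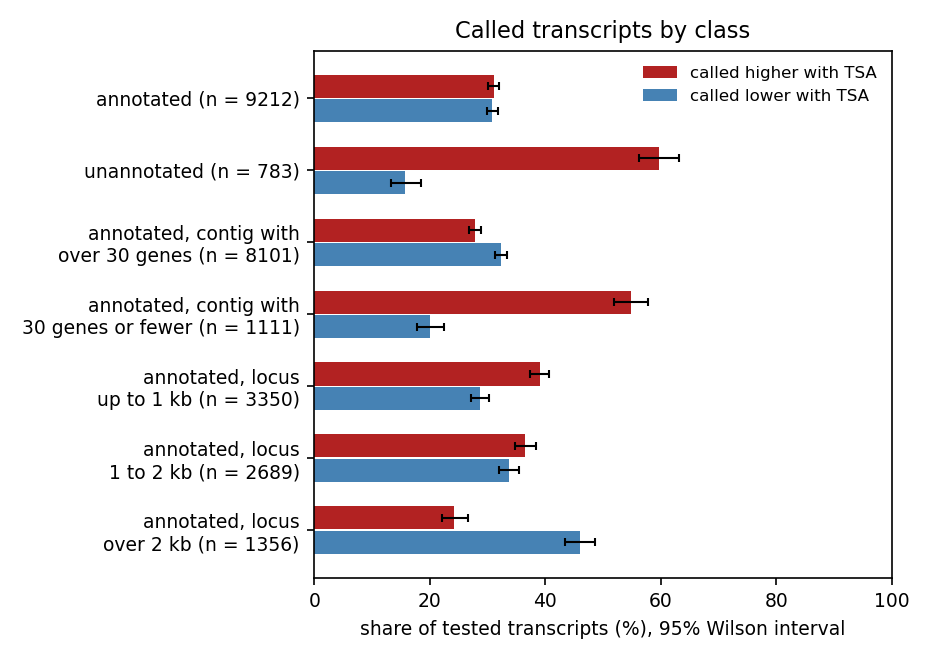
Share of tested transcripts (x axis, %) called higher or lower with TSA in 7 transcript classes (y axis, with the number tested); bars are shares and lines are 95% Wilson intervals, which cover counting error only. Higher calls are most frequent among unannotated transcripts (59.8%) and annotated transcripts on contigs with 30 genes or fewer (54.9%), and lower calls are most frequent in loci over 2000 bp (46.02%). Calls are those of the deposited adjusted p. The excess of lower calls in loci over 2000 bp was not seen with calls from the test statistic (odds ratio 0.958).

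No locus held transcripts called in opposite directions. Of 174 loci with at least 2 tested transcripts, 19 had at least 2 called transcripts, and in 0 of these were the calls of opposite direction. Of 10 annotated pseudogenes, 3 were tested and 0 were called by Cuffdiff at an adjusted or an unadjusted p of 0.05. In 5 transcripts called higher, the ethanol value is listed at 0, and 4 of these are unannotated.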

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

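Of the transcripts that Cuffdiff did not test, which enter none of the report's counts of calls, some stood well above the control and others well below it. Among those untested for want of reads, 45 had at least 10 FPKM with TSA and at least 4 times the ethanol value, and 21 showed the opposite. Among those marked as low data, 57 had at least 10 FPKM with TSA and at least 4 times the ethanol value, and 146 showed the opposite. These values carry no test.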

How the results depend on the processing

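The numbers of called transcripts stayed within 1.5 times of 3331 higher and 2964 lower under 11 of 13 alternatives, from 2454 to 3598 higher and from 2066 to 3174 lower. Among those 11, the 3 other scalings and the minimum of 1 FPKM left these counts and the odds ratios below unchanged. They are no check of either. The exceptions were a minimum change of 2-fold (2008 higher, 1903 lower) and Bonferroni adjustment (0 and 0), where the p floor of 5e-05 over 9995 tests cannot reach 0.05. Without adjustment, Cuffdiff's p was under 0.05 in 6558 tests. The median log2 change of all tested transcripts moved from 0.07 to -0.18 with a common sum and to 0.27 with a common sum over loci over 300 bp, by construction of these scalings. The odds ratio of higher calls stayed above 1 and past the threshold in every alternative that left calls (Bonferroni left none), from 3.16 to 4.22 for unannotated transcripts and from 1.87 (contigs with 100 genes or fewer) to 4.73 for contigs with few genes. The odds ratio of lower calls for loci over 2000 bp was 1.58 to 2.06, except 0.958 (two-sided Fisher's exact test, p = 0.556) with calls from the test statistic; the cause was not tested. The other scalings changed no direction of a call and could not be retested, so they say nothing of which transcripts would be called. Pseudocount, minimum FPKM and a common sum kept the direction of the 4 named genes, and pseudocount and minimum FPKM kept rho of length (-0.13 to -0.12). No value is known without either library of a condition. No paired analysis was possible because the labels give no replicate numbers (samples were numbered in accession order only to name them) and the table holds 1 value per condition. The test-statistic calls, the scaling over loci over 300 bp and the class bounds were chosen after seeing the data. So were the counts limited to loci over 300 bp or to annotated transcripts, and every alternative for the classes and for rho. Leave-one-out and the gene list alternatives were not run, for want of library values and product names.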

Other observations

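The tests of explanations reported here were chosen after the patterns were seen; the tests of genomic DNA, of run-on transcription, of shared reads and of length bias were also worded after the values they use had been seen.

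The changes of neighbouring loci were weakly correlated. Over 8853 pairs of adjacent, non-overlapping tested loci, Spearman's rho of the log2 changes was 0.20, against -0.03 to 0.03 in 200 random orders. It was 0.17 for gaps under 500 bp and 0.20 for 900 pairs at least 5000 bp apart. The 2 loci changed in the same direction in 56.2% of all pairs, in 62.6% of those at least 5000 bp apart and in 53.6% of annotated pairs on contigs with over 30 genes. No random range was computed for these shares. Loci far from their neighbours rose more often, which alone raises the share for wide gaps. Between these annotated pairs rho was 0.11, also above all 200 random orders. Stretches of at least 8 consecutive tested loci called in 1 direction numbered 20, of which 14 were higher with TSA and 6 lower. Random orders over all loci gave at most 8 such stretches (median 1), and random orders within each contig gave at most 17 (median 8). The longest observed stretch, 12 loci, was no longer than random orders gave (up to 16, or 19 within contigs).

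The stretches differed in composition, and some of the 20 are given here as examples. Most of those called higher lay on contigs with 30 annotated genes or fewer, such as KB207261 (26 genes) and KB206128 (17 genes). All of those called lower lay on contigs with more genes. The stretches are therefore not separate from the class of contigs with few genes. On contig KB207261, 12 loci between 3138 and 92167 were called higher, 4 of them unannotated, with a median log2 change of 1.64. On contig KB206128, 12 annotated loci between 26118 and 54099 were called higher, with a median log2 change of 1.55. On contig KB206320, 9 loci between 16380 and 94023, 7 of them unannotated, were called higher with a median log2 change of 2.19. On contig KB206398, 10 loci between 58994 and 80581 were called lower, with a median log2 change of -1.92. On contig KB207030, 8 annotated loci between 300686 and 323036 were called lower, with a median log2 change of -2.50.

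For the rise of unannotated transcripts, 3 technical explanations were tested. Genomic DNA spread evenly through the TSA libraries would lift annotated and unannotated loci alike. The loci compared had between 4.54 and 40.8 FPKM with ethanol. For 3070 annotated genes alone in their locus, tested or not, the median TSA minus ethanol difference was -0.050 FPKM (-0.44 to 0.37). For 391 unannotated transcripts it was 7.90 FPKM (6.40 to 10.1), but these were tested transcripts only. The sets were chosen by different rules, and part of the gap between them may come from that choice. The annotated value by itself showed no lift. Assembly from TSA reads alone does not account for the whole excess: with at least 10 FPKM in both conditions, a filter that itself removes transcripts rising from below it, the odds ratio of a higher call was 2.08 (1.69 to 2.56). Run-on from neighbouring genes predicts fewer rises far from genes, and the odds of a higher call were 2.24 times (1.57 to 3.19) as high beyond 1000 bp. Distance was not separated from contig type there, so the comparison does not settle the part of run-on. A response of these loci to TSA, the difference the design names, stays open and untested, as do multi-mapped reads from repeats.

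The rise of annotated genes on contigs with few genes resembles the unannotated class. The intervals below count transcripts as independent and are too narrow for a class set per contig. Low expression does not account for it as a whole: with at least 10 FPKM in both conditions, a filter that removes genes rising from below it, the odds ratio of a higher call was 1.98 (1.63 to 2.40), and the median log2 change of 0.72 lay above all 10000 lists matched on mean expression. Locus length does not account for the whole either, with an odds ratio of 2.50 (1.98 to 3.17) among one-transcript loci of 1000 to 2000 bp. Reads shared between repeated gene copies, which may be common on such contigs, cannot be told apart from a response of these regions, because no sequences were used. The share called higher, 54.9%, is the pattern itself and tests neither.

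The fall of long genes has a possible technical rival, which the values do not settle. In calls from the deposited p, its spread over contigs does not explain it, as the odds ratio of a lower call was 2.10 (1.84 to 2.39) on contigs with over 30 genes. In calls from the test statistic there was no excess to explain over all contigs (odds ratio 0.958, 0.833 to 1.10). A length bias from RNA fragmentation or library preparation cannot be told apart from biology: among the third of genes with the highest expression the median of loci over 2000 bp lay -0.30 (-0.49 to -0.11) from that of loci of 1000 bp or less, and among the third with the lowest expression -0.60 (-0.75 to -0.46). Spearman's rho of length and log2 change was -0.18, -0.11 and -0.01 (-0.05 to 0.03) in order of rising expression, so in abundant genes the median difference remained while the interval of rho included 0. The labels state an RNA integrity number above 8 for the samples; values per library were not analysed here.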
